A study of Mus musculus with 9 samples.

How the data were processed

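RNA of 9 samples of sorted mouse liver stroma, 3 each at E15.5, P5 and P10, was measured on Affymetrix arrays. Per the labels, total RNA was extracted with Trizol and labelled as biotinylated cRNA. The deposited values are log2 signals from robust multi-array averaging (RMA), which per the submitters' processing notes was run by the authors, and these notes also name Affymetrix Expression Console and Transcriptome Analysis Console 2.0. RMA corrects background, quantile-normalises probes between arrays and summarises them per probe set. No raw array files were used here, and the genome build behind the probe annotation is not given in the sources used here. Values ran from about 3 to 14 on the log2 scale. In any pair of arrays, 2.61% to 4.96% of probe sets had exactly equal values, and such ties lower the SD of those probe sets.

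Of 35556 probe sets, the probe annotation lists 23410, of which 21789 have 1 gene symbol and 1621 have several, and 12146 are not listed. Symbols were brought up to date by Entrez identifier for 21698 probe sets, from a RefSeq gene table used for names only. Each of 19938 genes was represented by its probe set with the highest mean over all 9 arrays, a choice that mattered for 999 genes with several probe sets. No filter on dim probe sets and no further scaling were applied to the reported values. Probe sets with no symbol or several symbols were left out of the gene comparisons and counted apart. Among named genes, 14 had several probe sets, in 21 pairs of gene and contrast. In 1 pair, Nlrc5 at P10 against E15.5, these were called in opposite directions. Some others differed in size. At P10 against E15.5 the lowest and highest were -3.71 and -2.59 for Foxf1, -2.15 and -1.35 for Pkm and -1.51 and -0.58 for Fga. Those of Bnip3, at 2.01 and 2.07, were close.

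Linear models with stage as the only term were fitted to all 9 arrays in limma 3.58.1 with statmod 1.5.0 under R 4.3.3 (6 residual and 2.22 prior degrees of freedom). Contrasts were P5 minus E15.5, P10 minus E15.5, P10 minus P5 and the difference between the intervals. The 2-sided moderated tests of limma were adjusted by Benjamini and Hochberg over all genes of a contrast, and genes with an adjusted p under 0.05 were called. A moderated F test compared the 3 stages. Arrays with the same replicate number in different stages were no more alike than others (Pearson r of residuals -0.079 to 0.069 across genes, 0 of 9 pairs over 0.1), so arrays were not paired. Errors of differences are standard errors from the model, and errors of means are SD over 3 arrays. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

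Gene lists were written from general knowledge of cell types and pathways. Of 36 lists, 35 were tested and 1, a sex check, was used only for values, and of 807 entries 731 were measured. The tested lists were niche factors, hepatic stellate cell, smooth muscle and myofibroblast, portal fibroblast, mesothelial cell, sinusoidal endothelial cell, hepatocyte, cholangiocyte, erythroid cell, macrophage, megakaryocyte, granulocyte, B and T lymphocyte, neural and Schwann cell, cell cycle, imprinted growth network, fetal RNA-binding and chromatin regulators, fibrillar collagen, basement membrane, matrix proteases, retinoid metabolism, TGF-beta and BMP, Wnt and hedgehog, interferon, antigen presentation, complement and acute phase, chemokines and cytokines, cholesterol, fatty acid, oxidative phosphorylation, glycolysis and hypoxia, ribosomal protein, immediate early and dissociation, circadian clock and glucocorticoid, and axon guidance genes. Lists were tested with camera in limma at a preset correlation of 0.01 between genes, with p adjusted over the 35 lists of a contrast. Camera with an estimated correlation and fry were alternatives. The test fry asks whether the genes of a list move 1 way on balance, or in either direction in its mixed form, and compares them with no other genes. Camera called 24, 20 and 23 lists in P5 against E15.5, P10 against E15.5 and P10 against P5, camera with an estimated correlation 4, 6 and 8, fry 27, 23 and 21, and its mixed form 33, 34 and 26. Member genes are counted at an adjusted p under 0.05 over all genes and adjusted over the list alone.

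The design, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names, per contrast, the 10 genes with the largest rise and the 10 with the largest decrease among called genes whose stages did not overlap and whose higher stage had a mean above the median of all genes, without predicted or uncharacterised genes. It adds up to 4 called members of each list with the smallest adjusted p, members that went the other way, and Cxcl12, Kitl, Lrat, Pdgfra, Ptprc, Alb, Pecam1, Mki67 and Igf2. It named 302 genes in 518 pairs of gene and contrast. Alternatives were quantile normalisation of the deposited values, centring on all genes or on ribosomal protein genes, a floor or filters at percentiles 30 and 50 of an array, other variance models, array weights, other choices of probe set, a replicate block, stricter thresholds, fits to only the compared stages, and fits without each array. Leaving out P5 arrays 2 and 3 together and adding the Eif2s3y level as a covariate were chosen after seeing the data.

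The fits were tested on simulated data with 200 of 19938 genes changed. Of genes changed by 0.5, 1 and 2 on the log2 scale, 41.8%, 86.6% and 98.5% were called in the right direction for P5 against E15.5, 43.3%, 91.0% and 95.5% for P10 against E15.5, and 55.2%, 95.5% and 98.5% for P10 against P5, with 5, 14 and 12 false calls. In the list simulation, run for P10 against P5, all 3 lists shifted by 0.5 were called, and 1 of 26 other lists. The simulated genes varied independently, whereas the estimated correlation between genes of a list reached 0.77 in the data. The simulation therefore does not show how often camera calls unchanged lists whose genes vary together.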

Results

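Stromal cells carrying a red fluorescent reporter for Cxcl12 were sorted from livers of C57BL/6 mice on embryonic day E15.5 and on postnatal days P5 and P10, and their RNA was measured on Affymetrix arrays, 3 per stage. The reporter, DsRed, was read from 1 Cxcl12 allele, and cells bearing CD45 or Ter119, surface markers of blood cells, were excluded. The fetal liver is a main site of blood formation, and this role passes to the bone marrow around birth. The comparisons address how the RNA of the Cxcl12-expressing stroma differed between these stages. The labels describe the 3 arrays of a stage as independent replicates. Nothing in them says whether each array came from a separate animal or pool, so the p-values measure the spread between these arrays.

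The median log2 signal lay between 6.22 and 6.45 on the 9 arrays, and their number limits the precision of every value. Pearson r across probe sets, which are not independent replicates, was 0.983 to 0.993 between arrays of 1 stage and 0.901 to 0.985 between arrays of different stages. The first principal component held 81.7% of the variance and parted the E15.5 arrays from the postnatal ones, and the second held 7.03% and parted P5 from P10. No array date or batch is given in the sources used here, so a batch that followed stage could not be told apart from stage. Ptprc, which encodes CD45, had mean log2 signals of 5.05 ± 0.073 (SD, n = 3) at E15.5, 5.11 ± 0.058 at P5 and 5.10 ± 0.086 at P10, below the median of all genes of 6.76. Cxcl12, the gene of the sort, had 10.98 ± 0.32, 10.17 ± 0.19 and 10.13 ± 0.16. Alb, the albumin gene of hepatocytes, had 13.14 ± 0.044, 13.20 ± 0.0091 and 13.13 ± 0.089, near the top of the scale at all stages. The arrays differed in sex signals: the Y-linked gene Eif2s3y had a log2 signal of 7.94 on E15.5 array 3, 8.98 and 9.24 on P5 arrays 2 and 3 and 8.97 on P10 array 1, and 3.96 to 4.14 on the other 5 arrays.

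From E15.5 to P5, several genes for ligands that act on blood stem cells fell, while genes of hepatocyte metabolism rose. Kitl, which encodes the ligand of the Kit receptor on blood stem cells, differed by -1.59 ± 0.15 on the log2 scale (P5 minus E15.5 ± SE, n = 3 per stage, adjusted p = 7.13e-05). Angpt1, a ligand of the Tie2 receptor, fell (-2.46 ± 0.16), as did the adhesion molecule Vcam1 (-2.03 ± 0.12) and the Notch ligand Jag1 (-2.01 ± 0.15). The growth factor genes Fgf1 (3.09 ± 0.14) and Igf1 (0.70 ± 0.13) rose. Alb was near the top of the scale on the same arrays, and which of the sorted cells expressed Fgf1 and Igf1 was not tested. Cxcl12 itself, given as a check of the sort, differed by -0.81 ± 0.17. Without P5 arrays 2 and 3, an omission chosen after seeing the data, P5 array 1 is the lone P5 array and is assumed to vary like the other stages. In that fit Cxcl12 differed by -0.67 ± 0.24 and did not pass (adjusted p = 0.0926), a loss that came with a smaller difference and the wider SE of a single array.

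Genes of hepatic stellate cells, the vitamin A storing pericytes of the liver, fell broadly at P5. In the list of hepatic stellate cell genes, of 34 measured members 2 rose, 26 fell and 6 did not pass (2 rose and 28 fell adjusted over the list alone). Their median difference was -1.47 (camera adjusted p = 2.45e-11 and adjusted p = 0.109 with an estimated correlation). The stellate transcription factor gene Lhx2 (-2.33 ± 0.097), the BMP ligand genes Bmp5 (-3.38 ± 0.16) and Gdf2 (-2.72 ± 0.13) and the mesenchymal regulator Foxf1 (-2.64 ± 0.13) were among them. Lrat, whose enzyme makes the stored retinyl esters, differed by -2.44 ± 0.21, and the mesenchymal growth factor receptor gene Pdgfra by -2.78 ± 0.21. Among immediate early and dissociation genes, which respond to sample handling, of 29 measured members 3 rose, 13 fell and 13 did not pass (3 rose and 13 fell adjusted over the list alone). That list had a median of -0.33 (camera adjusted p = 0.00774 and adjusted p = 0.121 with an estimated correlation). In the list of niche factors, of 26 measured members 3 rose, 10 fell and 13 did not pass (3 rose and 10 fell adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.0522 and adjusted p = 0.137 with an estimated correlation).

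Many matrix and contractile genes fell at P5. In the list of fibrillar collagens and collagen processing, of 29 measured members 0 rose, 25 fell and 4 did not pass (0 rose and 26 fell adjusted over the list alone), with a median of -1.09 (camera adjusted p = 1.26e-11 and adjusted p = 0.109 with an estimated correlation). Examples were the prolyl hydroxylase gene P4ha3 (-2.90 ± 0.14), the lysyl hydroxylase gene Plod2 (-2.62 ± 0.18) and the collagen chaperone gene Serpinh1 (-1.22 ± 0.088). In the basement membrane list, 3 rose and 11 fell of 18 (3 and 11 adjusted over the list alone), including Lamb1 (-1.63 ± 0.17) and, in the other direction, Col18a1 (0.77 ± 0.11). The basement membrane list had camera adjusted p = 0.00345 and adjusted p = 0.290 with an estimated correlation. Among matrix proteases and their inhibitors, 1 rose and 10 fell of 18 (1 and 11 adjusted over the list alone), including Adamts1 (-2.60 ± 0.13). The matrix proteases and inhibitors list had camera adjusted p = 0.000905 and adjusted p = 0.196 with an estimated correlation. In the smooth muscle and myofibroblast list, 0 rose and 9 fell of 16 (0 and 9 adjusted over the list alone), including the desmin gene Des (-1.85 ± 0.13) and Myl9 (-2.01 ± 0.23). The smooth muscle and myofibroblast list had camera adjusted p = 0.000292 and adjusted p = 0.235 with an estimated correlation.

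The named genes with the largest rise at P5 encode enzymes and secreted proteins of hepatocytes. Akr1c6, a steroid dehydrogenase gene, rose by 7.38 ± 0.058 (adjusted p = 1.44e-10), Cyp2e1 by 7.17 ± 0.084 and the gluconeogenic gene Fbp1 by 7.10 ± 0.068. Hao1 (6.62 ± 0.26), Cyp4a14 (6.64 ± 0.17) and the plasma protein genes Hrg (6.44 ± 0.13) and Fetub (6.22 ± 0.11) followed. Of the 10 genes named for the largest rise, 4 (Akr1c6, Hao1, Cyp4a14 and Fetub) had an E15.5 mean under percentile 30 of the E15.5 arrays (5.30 on average). Their rises may be understated, though no test against background was run. In the hepatocyte list, of 24 measured members 17 rose, 1 fell and 6 did not pass (19 rose and 1 fell adjusted over the list alone), with a median of 0.57 and a mean of 1.85 (camera adjusted p = 3.08e-08 and adjusted p = 0.137 with an estimated correlation). Among genes of fatty acid metabolism, 15 rose and 3 fell of 23 (17 and 3 adjusted over the list alone), with a median of 1.72 (camera adjusted p = 1.11e-06 and adjusted p = 0.0216 with an estimated correlation). The nuclear receptor genes Pparg (3.55 ± 0.063) and Ppara (3.46 ± 0.10) rose and the desaturase gene Scd2 (-3.46 ± 0.12) fell. In the oxidative phosphorylation list, 21 rose and 0 fell of 24 (21 and 0 adjusted over the list alone), including Sdhb (1.34 ± 0.087). The oxidative phosphorylation list had camera adjusted p = 3.08e-08 and adjusted p = 0.115 with an estimated correlation.

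Among the named genes, the largest decrease was that of Sema3a, which encodes a repulsive guidance cue for axons (-5.27 ± 0.11, 38.6-fold lower, adjusted p = 2.22e-08), followed by the kinase gene Nrk (-4.93 ± 0.12) and Arxes1 (-4.89 ± 0.23), whose P5 mean lay under percentile 30 of the P5 arrays. In the axon guidance and neurotrophin list, of 26 measured members 4 rose, 15 fell and 7 did not pass (4 rose and 16 fell adjusted over the list alone). The axon guidance and neurotrophin list had camera adjusted p = 5.16e-05 and adjusted p = 0.0244 with an estimated correlation. In the imprinted growth network, a set of mostly imprinted genes, read from 1 parental allele, of 23 measured members 0 rose, 18 fell and 5 did not pass (0 rose and 18 fell adjusted over the list alone), with a median of -1.62 (camera adjusted p = 4.91e-10 and adjusted p = 0.0119 with an estimated correlation). Asb4 (-4.41 ± 0.13), Igf2r (-2.97 ± 0.092) and Dlk1 (-2.83 ± 0.14) were examples, whereas Igf2 differed by -0.0069 ± 0.062 and did not pass (adjusted p = 0.947). Igf2 lay between 12.83 and 12.88 on the E15.5 and P5 arrays, near their percentile 99 (12.85 to 12.90). A difference so near the top of the scale may be understated. In the Wnt and hedgehog list, 3 rose and 16 fell of 30 (3 and 16 adjusted over the list alone), including Rspo3 (-3.41 ± 0.12), Sfrp2 (-2.77 ± 0.072) and, in the other direction, Axin2. The Wnt and hedgehog signalling list had camera adjusted p = 1.63e-05 and adjusted p = 0.0244 with an estimated correlation. In the TGF-beta and BMP list, 8 rose and 15 fell of 31 (8 and 15 adjusted over the list alone). The TGF-beta and BMP signalling list had camera adjusted p = 0.00649 and adjusted p = 0.109 with an estimated correlation. Among fetal RNA-binding and chromatin regulators, 0 rose and 7 fell of 12 (0 and 7 adjusted over the list alone), including Igf2bp1 (-2.17 ± 0.089). The fetal RNA-binding and chromatin regulators list had camera adjusted p = 0.00145 and adjusted p = 0.109 with an estimated correlation.

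Markers of other cell types moved apart at P5. In the mesothelial list, 8 rose and 2 fell of 16 (11 and 2 adjusted over the list alone), with the keratin gene Krt18 higher (2.20 ± 0.11) and Wt1 lower (-0.97 ± 0.097), and camera adjusted p = 0.00257 and adjusted p = 0.128 with an estimated correlation. In the cholangiocyte list, 5 rose and 0 fell of 8 (5 and 0 adjusted over the list alone), including Sox9 (1.85 ± 0.15). The cholangiocyte list had camera adjusted p = 0.00685 and adjusted p = 0.109 with an estimated correlation. In the erythroid list, 0 rose and 9 fell of 14 (0 and 9 adjusted over the list alone), including Slc4a1 (-1.47 ± 0.25). The erythroid cell list had camera adjusted p = 0.00386 and adjusted p = 0.436 with an estimated correlation. In the megakaryocyte list, 0 rose and 4 fell of 7 (0 and 6 adjusted over the list alone), including Pf4 (-2.72 ± 0.40). The megakaryocyte list had camera adjusted p = 0.00345 and adjusted p = 0.188 with an estimated correlation. In the cell cycle list, 0 rose and 22 fell of 39 (0 and 24 adjusted over the list alone), including Cenpe (-2.31 ± 0.29) and Mki67 (-1.54 ± 0.22). The cell cycle list had camera adjusted p = 4.78e-07 and adjusted p = 0.247 with an estimated correlation. In the sinusoidal endothelial list, 5 rose and 1 fell of 24 (3 and 1 adjusted over the list alone), with a median of 0.65 (camera adjusted p = 0.0358 and adjusted p = 0.735 with an estimated correlation). That call ended without E15.5 array 2, P5 array 2 or P5 array 3 (adjusted p from 0.0714 to 0.237), and without both P5 arrays 2 and 3, an omission chosen after seeing the data that leaves 1 P5 array, the median was -0.053. The endothelial adhesion gene Pecam1 differed by 0.66 ± 0.21 (adjusted p = 0.0394), and this call held only without P5 array 1 or P10 array 1 among the 9 fits that left out 1 array (adjusted p from 0.0547 to 0.116 in the other 7). Xist, the X-inactivation RNA of female cells, differed by -3.79 ± 1.01. Its log2 signal was 10.51 and 10.64 on E15.5 arrays 1 and 2 and 10.16 on E15.5 array 3, which also carried the Y-linked signal. It was 6.16 and 5.03 on P5 arrays 2 and 3 and 5.09 on P10 array 1, which carried that signal too. On the postnatal arrays without it, Xist lay at 8.75 (P5 array 1), 7.81 and 7.98 (P10 arrays 2 and 3), below E15.5 arrays 1 and 2. The Xist call ended when E15.5 array 1, E15.5 array 2, P5 array 2 or P5 array 3 was left out (adjusted p from 0.0555 to 0.0576).

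Across 19938 genes, limma called 3560 higher and 3529 lower at P5 than at E15.5 at an adjusted p under 0.05, 35.6% of the genes. Of these, 1435 and 1356 differed by at least 2-fold. The 3 arrays of 1 stage lay wholly above the 3 of the other for 9009 genes (45.2%), where chance gives 10%. Of the called genes 50.2% were higher, a share that became 64.1% after quantile normalisation and 61.4% after centring each array on its ribosomal protein genes, so the balance of directions depended on the scaling.

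**Figure D1:**
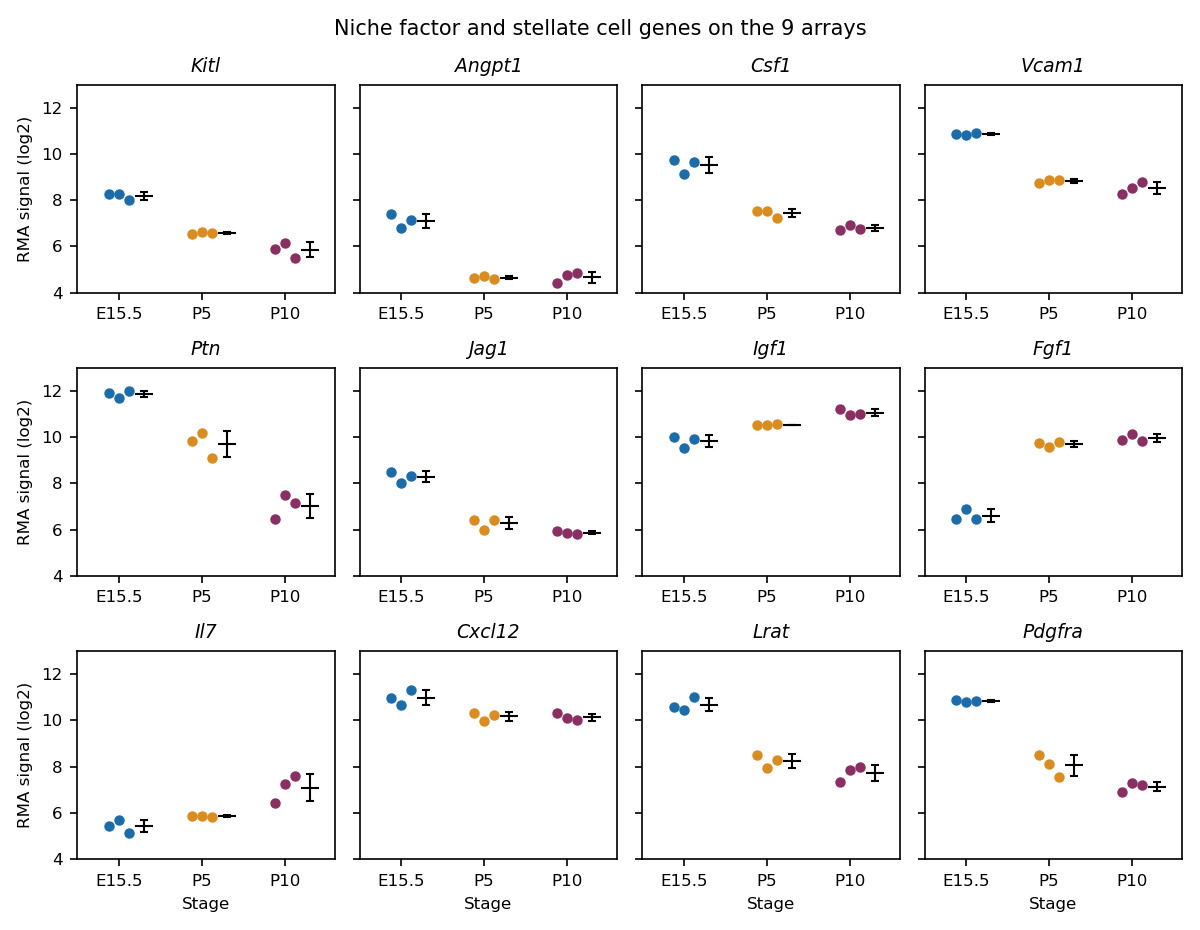
RMA log2 signal (y axis) of 12 genes from the niche factor and hepatic stellate cell lists at E15.5, P5 and P10 (x axis). Points give the 3 arrays of each stage and black lines the mean ± SD. Kitl lay between 7.99 and 8.28 on the E15.5 arrays and between 5.50 and 6.14 on the P10 arrays.

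Between E15.5 and P10, Kitl and most stellate list genes fell, and several metabolic genes of hepatocytes rose. Kitl differed by -2.33 ± 0.15 (5.02-fold lower, adjusted p = 5.41e-06). Csf1, the growth factor gene of macrophages, fell (-2.73 ± 0.16), as did Vcam1 (-2.35 ± 0.12), Jag1 (-2.43 ± 0.15) and the secreted growth factor gene Ptn (-4.83 ± 0.31). Fgf1 (3.35 ± 0.14), Igf1 (1.24 ± 0.13) and the lymphoid cytokine gene Il7 (1.67 ± 0.27) rose, and which of the sorted cells expressed them was not tested. In the niche factor list, of 26 measured members 4 rose, 11 fell and 11 did not pass (4 rose and 13 fell adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.0280 and adjusted p = 0.105 with an estimated correlation).

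In the hepatic stellate cell list at P10, of 34 measured members 1 rose, 26 fell and 7 did not pass (2 rose and 27 fell adjusted over the list alone), with a median of -1.62 (camera adjusted p = 3.91e-12 and adjusted p = 0.0801 with an estimated correlation). Foxf1 (-3.71 ± 0.13), Gdf2 (-3.27 ± 0.13), Lhx2 (-2.89 ± 0.097) and the adhesion molecule gene Alcam (-2.71 ± 0.093) fell, and Lrat differed by -2.95 ± 0.21 and Pdgfra by -3.69 ± 0.21. In the list of fibrillar collagens and collagen processing, of 29 measured members 0 rose, 27 fell and 2 did not pass (0 rose and 28 fell adjusted over the list alone), with a median of -1.58 (camera adjusted p = 2.60e-15 and adjusted p = 0.0704 with an estimated correlation). The type I collagen gene Col1a1 (-1.63 ± 0.080) and the lysyl oxidase gene Lox (-2.37 ± 0.10) were among them. In the basement membrane list, 0 rose and 13 fell of 18 (2 and 13 adjusted over the list alone), including Nid1 (-2.61 ± 0.18). The basement membrane list had camera adjusted p = 4.61e-06 and adjusted p = 0.125 with an estimated correlation. Among matrix proteases and inhibitors, 2 rose and 11 fell of 18 (2 and 11 adjusted over the list alone), including Timp2 (-2.60 ± 0.11) and, in the other direction, Mmp19 (1.26 ± 0.13). The matrix proteases and inhibitors list had camera adjusted p = 1.74e-05 and adjusted p = 0.125 with an estimated correlation. In the smooth muscle and myofibroblast list, 0 rose and 11 fell of 16 (0 and 12 adjusted over the list alone), including Myl9 (-2.88 ± 0.23). The smooth muscle and myofibroblast list had camera adjusted p = 1.33e-05 and adjusted p = 0.179 with an estimated correlation. In the portal fibroblast list, 0 rose and 7 fell of 17 (1 and 7 adjusted over the list alone), including Fbln1 (-1.86 ± 0.081). The portal fibroblast list had camera adjusted p = 0.0168 and adjusted p = 0.377 with an estimated correlation. In the mesothelial list, 2 rose and 8 fell of 16 (2 and 9 adjusted over the list alone), including Wt1 (-2.21 ± 0.097). The mesothelial cell list had camera adjusted p = 0.0227 and adjusted p = 0.220 with an estimated correlation.

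**Figure D2:**
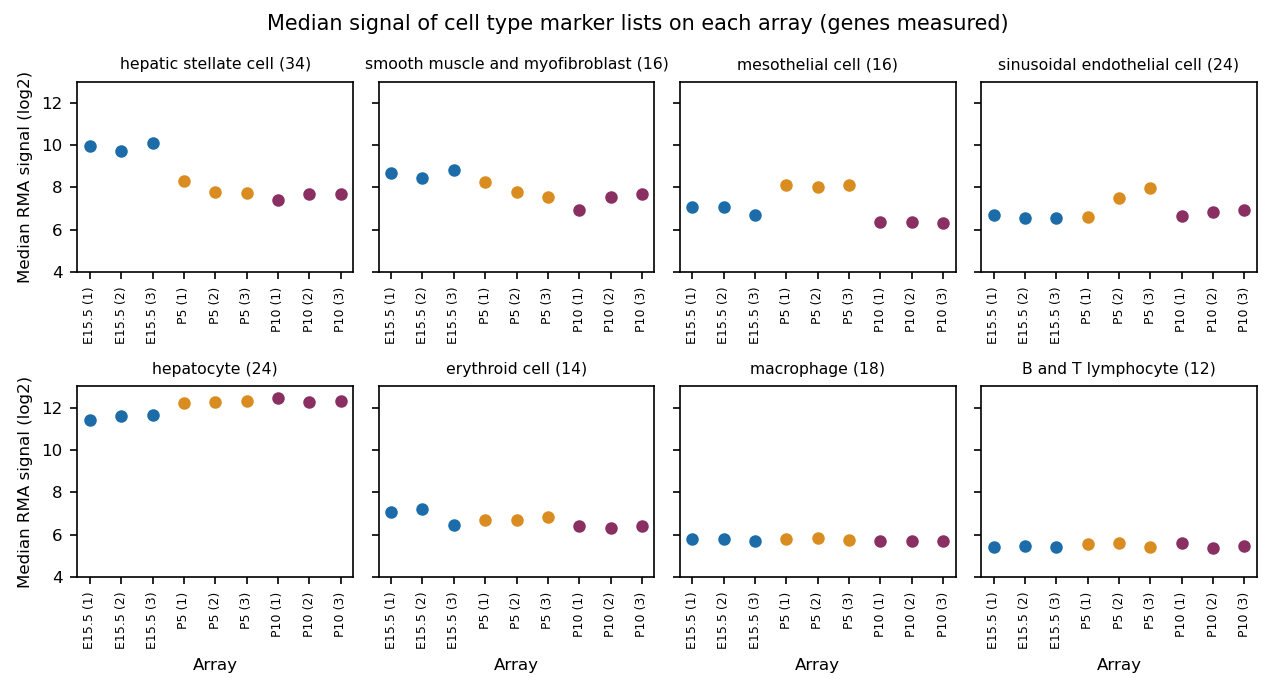
Median RMA log2 signal (y axis) of the measured members of 8 cell-type gene lists on each of the 9 arrays, grouped by stage (x axis), with 1 point per array. The sinusoidal endothelial list lay at 6.60 on P5 array 1 and at 7.97 on P5 array 3.

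Several hepatocyte enzymes that led at P5 also led at P10. Akr1c6 (7.72 ± 0.058, adjusted p = 9.88e-11) and Fbp1 (7.23 ± 0.068) were joined by the tryptophan dioxygenase gene Tdo2 (7.14 ± 0.23), the gluconeogenic gene Pck1 (6.62 ± 0.14), the tyrosine aminotransferase gene Tat (6.62 ± 0.12) and the urate oxidase gene Uox (6.53 ± 0.28). With E15.5 means of 4.91 for Akr1c6 and 4.66 for Tdo2, under percentile 30 of the E15.5 arrays, these 2 rises may be understated. In the hepatocyte list, of 24 measured members 12 rose, 4 fell and 8 did not pass (13 rose and 4 fell adjusted over the list alone), with a median of 0.17 and a mean of 1.74 (camera adjusted p = 0.00149 and adjusted p = 0.397 with an estimated correlation). The plasma protein genes Afp (-2.58 ± 0.13) and Apob (-0.91 ± 0.14) were among those that fell. Alb, Apoa1, Apoa2 and Ttr were in the top 1% of probe sets on all 9 arrays. Their differences from E15.5 may be understated at P5 and P10, and the median of the hepatocyte list with them. Among genes of fatty acid metabolism, 15 rose and 2 fell of 23 (15 and 3 adjusted over the list alone), including Ppara (3.94 ± 0.10). The fatty acid metabolism and lipid handling list had camera adjusted p = 5.26e-06 and adjusted p = 0.0151 with an estimated correlation. In the oxidative phosphorylation list, 23 rose and 0 fell of 24 (23 and 0 adjusted over the list alone), with a median of 0.75 (camera adjusted p = 5.20e-10 and adjusted p = 0.0765 with an estimated correlation). In the list of circadian clock and glucocorticoid response, 15 rose and 1 fell of 23 (15 and 1 adjusted over the list alone), including Bhlhe40 (2.72 ± 0.25) and Hlf (2.50 ± 0.086). The circadian clock and glucocorticoid response list had camera adjusted p = 0.000128 and adjusted p = 0.0765 with an estimated correlation. In the retinoid metabolism list, genes went both ways: 8 rose and 6 fell of 23 (8 and 7 adjusted over the list alone), with the alcohol dehydrogenase gene Adh1 higher (5.22 ± 0.19) and Crabp1 lower (-2.74 ± 0.31), and the list as a whole did not pass (camera adjusted p = 0.569 and adjusted p = 0.825 with an estimated correlation).

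Imprinted genes showed the largest decrease of any list at P10. In the imprinted growth network, of 23 measured members 0 rose, 20 fell and 3 did not pass (0 rose and 21 fell adjusted over the list alone), with a median of -2.29 (camera adjusted p = 3.81e-14 and adjusted p = 0.00427 with an estimated correlation). The noncoding RNA genes Rian (-5.39 ± 0.43) and Meg3 (-4.86 ± 0.21), the transcription factor gene Plagl1 (-4.89 ± 0.17) and the Notch ligand homologue Dlk1 (-4.67 ± 0.14) fell, with the P10 mean of Rian under percentile 30 of the P10 arrays, and Igf2 differed by -0.27 ± 0.062 (adjusted p = 0.00807). Outside that list, the named genes with the largest decreases were Nrk (-6.02 ± 0.12) and Sema3a (-5.48 ± 0.11). In the axon guidance list, 2 rose and 17 fell of 26 (3 and 17 adjusted over the list alone). The axon guidance and neurotrophin list had camera adjusted p = 5.92e-07 and adjusted p = 0.0117 with an estimated correlation. In the Wnt and hedgehog list, 2 rose and 17 fell of 30 (2 and 17 adjusted over the list alone), including Gli3 (-2.80 ± 0.094). The Wnt and hedgehog signalling list had camera adjusted p = 5.68e-07 and adjusted p = 0.0117 with an estimated correlation. In the TGF-beta and BMP list, 2 rose and 18 fell of 31 (3 and 19 adjusted over the list alone), including Tgfbr3 (-3.07 ± 0.10). The TGF-beta and BMP signalling list had camera adjusted p = 1.41e-05 and adjusted p = 0.0215 with an estimated correlation. Among fetal RNA-binding and chromatin regulators, 0 rose and 7 fell of 12 (0 and 8 adjusted over the list alone), including Hmga2 (-2.20 ± 0.21). The fetal RNA-binding and chromatin regulators list had camera adjusted p = 0.000137 and adjusted p = 0.0502 with an estimated correlation. In the immediate early and dissociation list, 2 rose and 17 fell of 29 (2 and 20 adjusted over the list alone), including Ccn1 (-3.93 ± 0.26). The immediate early and dissociation response list had camera adjusted p = 1.51e-05 and adjusted p = 0.0339 with an estimated correlation.

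Most genes of the erythroid and megakaryocyte lists fell at P10, and few genes of other blood cells passed. In the erythroid list, 1 rose and 10 fell of 14 (1 and 10 adjusted over the list alone), including Slc4a1 (-1.71 ± 0.25). The erythroid cell list had camera adjusted p = 0.00748 and adjusted p = 0.530 with an estimated correlation. In the megakaryocyte list, 0 rose and 4 fell of 7 (0 and 6 adjusted over the list alone), including Pf4 (-2.53 ± 0.40). The megakaryocyte list had camera adjusted p = 0.00383 and adjusted p = 0.194 with an estimated correlation. The macrophage list did not pass (camera adjusted p = 0.600 and adjusted p = 0.825 with an estimated correlation), and 1 rose and 2 fell of 18 (0 and 2 adjusted over the list alone), including Cd68 (-1.09 ± 0.14). In the granulocyte list, 2 rose and 0 fell of 13 (2 and 0 adjusted over the list alone), including Lcn2 (3.05 ± 0.53). The granulocyte list had camera adjusted p = 0.527 and adjusted p = 0.825 with an estimated correlation. In the B and T lymphocyte list, 1 rose and 0 fell of 12 (1 and 0 adjusted over the list alone). The B and T lymphocyte list had camera adjusted p = 0.695 and adjusted p = 0.852 with an estimated correlation. In the neural and Schwann cell list, 0 rose and 1 fell of 7 (0 and 1 adjusted over the list alone), the gene that fell being Fabp7 (-3.30 ± 0.11). Of the cell cycle list, 6 rose and 7 fell of 39 (5 and 7 adjusted over the list alone), and it did not pass (camera adjusted p = 0.270 and adjusted p = 0.825 with an estimated correlation), though Mki67 fell (-1.22 ± 0.22). Pecam1 differed by 0.21 ± 0.21 and did not pass (adjusted p = 0.492). The neural list had a median of 0.047 and a mean of -0.32, opposite in sign, and did not pass (camera adjusted p = 0.940 and adjusted p = 0.971 with an estimated correlation). The ribosomal protein list, a reference for scaling, had a median of -0.084 and did not pass (camera adjusted p = 0.146 and adjusted p = 0.825 with an estimated correlation).

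Across all genes, 3998 were called higher and 3718 lower at P10 than at E15.5, 38.7% of the 19938, with 1807 and 1636 differing by at least 2-fold. The arrays of the stages did not overlap for 10312 genes (51.7%, where chance gives 10%). Of the called genes 51.8% were higher, a share that became 69.4% after quantile normalisation and 65.6% after centring on the median of all genes, and quantile normalisation moved the median of all genes from 0.024 to 0.15.

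From P5 to P10, most genes of the mesothelial and imprinted lists fell. Upk1b, a mesothelial membrane protein gene, differed by -2.96 ± 0.13 (P10 minus P5, n = 3 per stage, adjusted p = 7.31e-05), and Upk3b (-2.42 ± 0.16), the mesothelial regulator Wt1 (-1.24 ± 0.097) and Msln, which encodes mesothelin (-2.51 ± 0.26), also fell. In the mesothelial list, of 16 measured members 0 rose, 11 fell and 5 did not pass (0 rose and 15 fell adjusted over the list alone), with a median of -1.01 (camera adjusted p = 1.31e-18 and adjusted p = 0.00681 with an estimated correlation). In the imprinted growth network, of 23 measured members 0 rose, 15 fell and 8 did not pass (0 rose and 15 fell adjusted over the list alone), with a median of -1.18 (camera adjusted p = 5.81e-19 and adjusted p = 0.00175 with an estimated correlation). Meg3 (-2.51 ± 0.21), Plagl1 (-2.28 ± 0.17), Dlk1 (-1.84 ± 0.14) and Mest (-1.81 ± 0.14) were examples. Igf2 differed by -0.26 ± 0.062 (adjusted p = 0.0480), a call that ended without any 1 of the 9 arrays (adjusted p from 0.0652 to 0.118).

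Of the niche factors, 2 rose and 3 fell of 26 (2 and 4 adjusted over the list alone), and the niche list passed narrowly (camera adjusted p = 0.0455 and adjusted p = 0.112 with an estimated correlation). That list call ended without E15.5 array 2 or 3, P5 array 1 or 3 or P10 array 1 (adjusted p from 0.0510 to 0.123). Ptn fell (-2.66 ± 0.31, adjusted p = 0.00307). Kitl differed by -0.74 (SE 0.15), Il7 rose by 1.22 ± 0.27 and Igf1 by 0.54 ± 0.13, whereas Cxcl12 differed by -0.037 ± 0.17 and did not pass (adjusted p = 0.951). The Kitl call ended without E15.5 array 1, any 1 of the P5 arrays or P10 array 1 (adjusted p from 0.0545 to 0.0879). The Il7 call ended without any 1 array other than E15.5 array 3 and P10 array 1 (0.0522 to 0.124), and the Igf1 call without any 1 array other than E15.5 array 2 (0.0537 to 0.130) and after quantile normalisation (0.0752) or ribosomal centring (0.0554). Lrat differed by -0.52 ± 0.21 and did not pass (adjusted p = 0.249). Pdgfra differed by -0.91 ± 0.21 (adjusted p = 0.0457), a call that ended without any 1 array other than P5 array 3 (adjusted p from 0.0716 to 0.129). In the hepatic stellate cell list, 0 rose and 7 fell of 34 (0 and 9 adjusted over the list alone), including the filament gene Vim (-1.49 ± 0.13) and Alcam (-0.98 ± 0.093). The hepatic stellate cell list had camera adjusted p = 4.47e-05 and adjusted p = 0.238 with an estimated correlation.

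Some matrix genes fell between P5 and P10. In the list of fibrillar collagens and collagen processing, of 29 measured members 0 rose, 11 fell and 18 did not pass (0 rose and 18 fell adjusted over the list alone), with a median of -0.55 (camera adjusted p = 1.54e-16 and adjusted p = 0.0510 with an estimated correlation). Lox (-1.19 ± 0.10), Col1a1 (-0.91 ± 0.080) and Col3a1 (-0.93 ± 0.10) were among them. In the basement membrane list, 0 rose and 8 fell of 18 (0 and 12 adjusted over the list alone), including Lama5 (-0.51 ± 0.083). The basement membrane list had camera adjusted p = 8.34e-10 and adjusted p = 0.0603 with an estimated correlation. Among matrix proteases and inhibitors, 0 rose and 6 fell of 18 (0 and 7 adjusted over the list alone), including Timp2 (-1.67 ± 0.11). The matrix proteases and inhibitors list had camera adjusted p = 2.56e-07 and adjusted p = 0.0761 with an estimated correlation. In the portal fibroblast list, 0 rose and 6 fell of 17 (1 and 13 adjusted over the list alone), including Fbln1 (-0.65 ± 0.081). The portal fibroblast list had camera adjusted p = 4.14e-10 and adjusted p = 0.0477 with an estimated correlation. In the smooth muscle and myofibroblast list, 0 rose and 3 fell of 16 (0 and 7 adjusted over the list alone). The smooth muscle and myofibroblast list had camera adjusted p = 4.15e-05 and adjusted p = 0.180 with an estimated correlation. In the TGF-beta and BMP list, 0 rose and 9 fell of 31 (0 and 13 adjusted over the list alone), including Id3 (-1.67 ± 0.20). The TGF-beta and BMP signalling list had camera adjusted p = 8.63e-10 and adjusted p = 0.00681 with an estimated correlation. In the Wnt and hedgehog list, 0 rose and 5 fell of 30 (0 and 9 adjusted over the list alone), including Sfrp1 (-1.46 ± 0.19). The Wnt and hedgehog signalling list had camera adjusted p = 1.83e-06 and adjusted p = 0.0104 with an estimated correlation. In the axon guidance list, 0 rose and 5 fell of 26 (0 and 6 adjusted over the list alone), including Sema5a (-0.72 ± 0.10). The axon guidance and neurotrophin list had camera adjusted p = 9.65e-07 and adjusted p = 0.0104 with an estimated correlation. In the immediate early and dissociation list, 0 rose and 5 fell of 29 (1 and 12 adjusted over the list alone). The immediate early and dissociation response list had camera adjusted p = 2.58e-06 and adjusted p = 0.0213 with an estimated correlation.

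From P5 to P10 the cytochrome P450 genes Cyp2c29 (4.44 ± 0.22, adjusted p = 0.000128) and Cyp2c55 (2.63 ± 0.10) rose. Their P5 means of 5.15 and 4.78 lay under the average percentile 30 of the P5 arrays (5.19), so these rises may be understated. The ornithine aminotransferase gene Oat (2.25 ± 0.29) and the uridine phosphorylase gene Upp2 (2.11 ± 0.21) also rose. Hamp fell by more than any other named gene (-4.80 ± 0.66, adjusted p = 0.00572). It encodes the iron hormone hepcidin, and against P5 array 1 alone, a fit chosen after seeing the data that takes the spread from the other stages, it differed by -4.53 ± 1.06 and did not pass (adjusted p = 0.0798). In the hepatocyte list, 3 rose and 8 fell of 24 (4 and 9 adjusted over the list alone), with Pck1 higher (0.99 ± 0.14) and Afp lower (-2.14 ± 0.13), and camera adjusted p = 0.00305 and adjusted p = 0.422 with an estimated correlation. The hepatocyte list call ended without P5 array 3 (adjusted p = 0.0691). In the cholangiocyte list, 0 rose and 4 fell of 8 (0 and 6 adjusted over the list alone), including Krt19 (-1.71 ± 0.20). The cholangiocyte list had camera adjusted p = 2.03e-05 and adjusted p = 0.0213 with an estimated correlation. In the cell cycle list, 6 rose and 0 fell of 39 (19 and 0 adjusted over the list alone), including Mcm6 (0.59 ± 0.073), whereas Mki67 differed by 0.32 ± 0.22 and did not pass (adjusted p = 0.552). The cell cycle list had camera adjusted p = 1.10e-13 and adjusted p = 0.110 with an estimated correlation. In the oxidative phosphorylation list, 3 rose and 0 fell of 24 (12 and 0 adjusted over the list alone). The oxidative phosphorylation list had camera adjusted p = 3.80e-08 and adjusted p = 0.0899 with an estimated correlation. In the circadian clock and glucocorticoid list, 2 rose and 0 fell of 23 (8 and 0 adjusted over the list alone). The circadian clock and glucocorticoid response list had camera adjusted p = 0.000414 and adjusted p = 0.0809 with an estimated correlation. Among fetal RNA-binding and chromatin regulators, 0 rose and 2 fell of 12 (1 and 4 adjusted over the list alone). The fetal RNA-binding and chromatin regulators list had camera adjusted p = 0.0173 and adjusted p = 0.114 with an estimated correlation, and this call ended without P5 array 2 (adjusted p = 0.0505). In the sinusoidal endothelial list, 0 rose and 1 fell of 24 (0 and 1 adjusted over the list alone), with a median of -0.45 (camera adjusted p = 2.00e-05 and adjusted p = 0.427 with an estimated correlation). With P5 arrays 2 and 3 left out, chosen after seeing the data, that median was 0.22, a reversal that rests on P5 array 1 alone.

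Between P5 and P10 limma called 550 genes higher and 576 lower, 5.65% of the 19938, with 79 and 162 differing by at least 2-fold. Without P10 array 2 the counts were 250 higher and 336 lower, and other single arrays moved the higher count by more than 1.5 times: it was 346 without P5 array 2, 355 without P10 array 1 and 334 without P10 array 3. The stages did not overlap for 4035 genes (20.2%, where chance gives 10%), and of the called genes 48.8% were higher, 63.5% after centring on the median of all genes and 40.4% after centring on ribosomal protein genes.

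**Figure D3:**
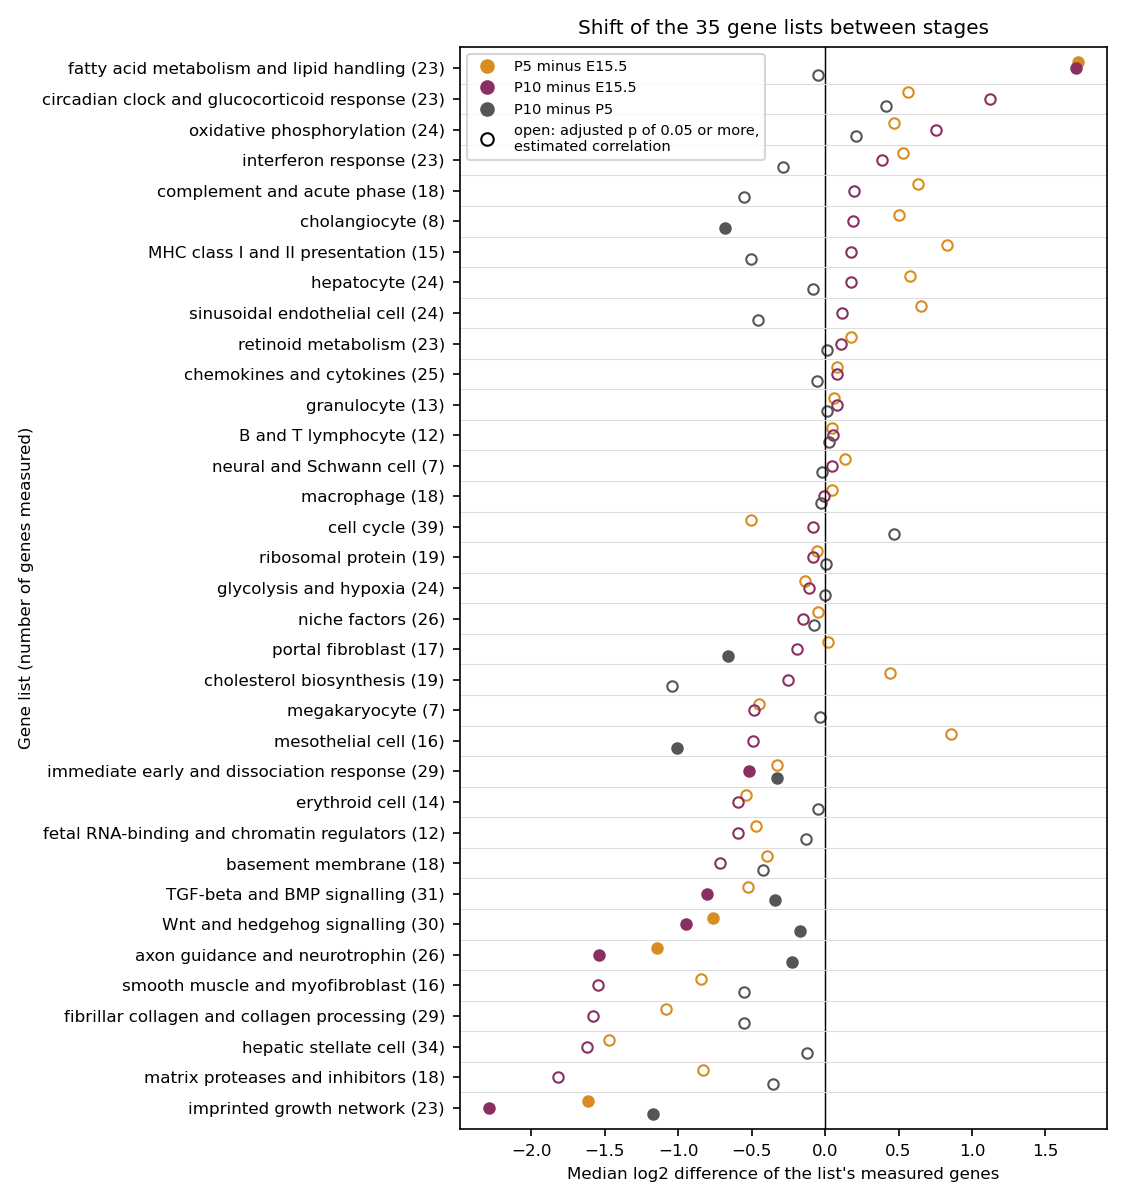
Median log2 difference (x axis) of the measured members of 35 gene lists (y axis) for P5 minus E15.5, P10 minus E15.5 and P10 minus P5, with 1 point per list and contrast, filled where camera with an estimated correlation gave an adjusted p under 0.05. The imprinted growth network lay at -1.62, -2.29 and -1.18 and was filled in all 3 contrasts.

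In 4 lists at P5 and 2 at P10 against E15.5, and in 7 at P10 against P5, the median, the mean and the camera direction differed in sign, and none of these lists passed. Genes that differed from E15.5 did so largely in the same direction at both postnatal stages. Of the genes called higher, 3101 were shared by P5 and P10, among them Akr1c6, Fbp1, Pparg and Fgf1, and of those called lower 3044 were shared, among them Kitl, Foxf1, Sema3a and Dlk1. Independent lists of the same sizes would share 713.9 and 658.1. Both contrasts use the same 3 E15.5 arrays, which cannot be split, and simulated unchanged groups set against them shared 0 on average in 100 simulations. These groups were centred on the observed E15.5 means, which leaves out the chance error of the E15.5 arrays. The simulation therefore cannot show how much overlap the shared arrays add by chance. Another 15 genes passed in opposite directions. The moderated F test of limma called 7634 genes across the 3 stages, and 316 genes rose and 368 fell in both intervals. P5 lay above both other stages for 114 genes, among them Msln, Krt19 and Sox9, and below both for 91, among them Mcm6 and Pcna. For 3316 genes the difference from P5 to P10 itself differed from that from E15.5 to P5, intervals of unequal length.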

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

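The tests of cell-type shares and of scaling on the stellate, hepatocyte and endothelial patterns were chosen after the results were seen, whereas the test on sex and the counts of other splits of the arrays were chosen before.

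Outside the 19938 genes, 3616 of 13767 probe sets with no gene symbol or several were called at P10 against E15.5, 1147 higher and 2469 lower (26.3%), in data that the gene comparisons did not use. The same set gave 3045 calls at P5 against E15.5 and 19 at P10 against P5. What these probe sets measure was not tested. Among the genes, 3316 differed between intervals: the difference from P5 to P10 was not that from E15.5 to P5 by a contrast of the differences in limma. Krt19 was an example, at 1.51 ± 0.20 from E15.5 to P5 and -1.71 ± 0.20 from P5 to P10 (adjusted p = 0.000502 for the difference between intervals).

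Hepatic stellate cell genes were lower at P10 than at E15.5, with a median of -1.62 over 34 members, 8 of which another list also holds. A smaller share of stromal RNA as the whole cause would lower them all by 1 amount, if stroma alone expressed them and signals were proportional to RNA. Of 24 members with an E15.5 mean between 8 and 12, which ranged from -3.93 to 0.72, 16 lay more than 3 SE from their median of -2.35. Neither condition was tested, so this spread does not rule out a smaller share as the whole cause. The highest median of the list under any scaling tried was -1.52. The values had already been normalised by RMA, and the scalings shifted the differences of all genes by a median of at most 0.12. This argues only against a scaling difference left after RMA. From P5 to P10, where the list moved less, 6 of the 24 lay more than 3 SE from their median. A changed mix of the sorted cells may still account for part or all of the decrease. A difference with age in the stroma itself stays open and untested, and a batch that followed stage cannot be told apart from it.

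Several of the 24 measured hepatocyte genes, 2 of them in another list, were among those with the largest rise at P10 against E15.5, with a list median of 0.17, in cells sorted for DsRed, a gate that should remove hepatocytes lacking the reporter. Alb, Apoa1, Apoa2 and Ttr, 4 of the 24, were in the top 1% of probe sets on all 9 arrays, with mean log2 signals above 13 at each stage, which is consistent with hepatocyte RNA in the sorted fraction at every stage. A larger share of hepatocyte RNA in the sorted fraction as the whole cause would lower none of these genes, but 4 of the 24 were called lower, Afp (-2.58 ± 0.13), Apob (-0.91 ± 0.14), Fga (-0.58 ± 0.14) and Ambp (-0.40 ± 0.086), and at least 4 under each scaling tried. A larger share as part of the cause stays open, as does whether the reporter cells themselves expressed these genes. Maturation of hepatocyte expression with age may account for the rise and was not tested.

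Sinusoidal endothelial genes were higher on P5 arrays 2 and 3 than on P5 array 1 for 24 of 24 members, 9 of them by at least 1 on the log2 scale. In the macrophage and mesothelial lists, 1 of 18 and 10 of 16 members were higher on both. The gate excluded CD45 and Ter119 but no endothelial marker, although it required DsRed and should remove endothelial cells lacking the reporter. Abundant members at P5, Gpr182 (9.17 ± 0.80, SD) and Clec4g (8.61 ± 1.72), a pair chosen after their values were seen, varied widely. Endothelial RNA in these fractions may be the source, but the count of 24 and this pair restate the pattern and are no separate support. P5 arrays 2 and 3 also carried the Y-linked signal, whereas on P10 array 1, which did so too, the endothelial median was -0.28 from the higher of the others. On E15.5 array 3 the endothelial median was 6.57 against 6.70 and 6.54. That array carried both the Y-linked signal and a high Xist signal (10.16), so it cannot stand for male animals alone. The bound, set after the pattern was seen, asked too little, since it rested on 1 array of another stage. A difference between male and female animals therefore cannot be told apart from another between the P5 animals or pools.

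Other splits of the same arrays were counted. In each contrast of 3 against 3 arrays only 10 splits exist, too few for a share under 0.05. Among the 10 splits, 1, the real one, gave as many genes: 7089 at P5 against E15.5 (highest other 0), 7716 at P10 against E15.5 (highest other 0) and 1126 at P10 against P5 (highest other 1). For lists 1 of 10 splits gave as many: 24, 20 and 23, with 19, 18 and 16 as the highest others. Camera at the preset correlation thus called many lists in wrong splits too, where at most 0, 0 and 1 genes were called. Wrong splits still set 2 arrays of a stage against 1, so part of the stage difference remained in them. A camera call at the preset correlation alone is therefore weak ground for a shift between stages. Of 100 splits of all 9 arrays, 1 gave as many as the 7634 genes of the F test (highest other 6190), a share under 0.05. For the 6145 genes shared by both contrasts against E15.5, 1 of 100 gave as many (highest other 22). That count depends on which arrays serve as the reference, and splits that differed only in this were counted as 1. No conclusion about chance is drawn from it. For the 3316 genes that differ between intervals 2 of 100 gave as many, a share under 0.05, but the highest other gave 7467 genes. That split was the 1 of 99 others that kept the E15.5 arrays together, and it also gave the highest F count. With E15.5 arrays mixed, the highest counts were 30 for F and 132 for the intervals. The distance of E15.5 from both postnatal stages is thus a structure of these samples that the F and interval counts carry.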

How the results depend on the processing

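Leaving out P5 arrays 2 and 3 and adding the Eif2s3y level as a covariate were chosen after the results were seen, and the first leaves P5 array 1 alone at P5, assumed to vary like the other stages. Of 488 called pairs of named gene and contrast, 397 kept direction and call under the alternatives fixed for them before the data were examined (scalings, floor, variance models, array weights, mean of probe sets, 2-stage fits, replicate block and fits without 1 array), and 381 also under those chosen later. Calls ended for 79 in at least 1 fit without 1 array (40 of the 107 at P10 against P5), 77 without P5 arrays 2 and 3, 74 without variance moderation, 47 with only 2 stages in the fit, 33 with the covariate, 30 with the replicate block and 14 after quantile normalisation. Nlrc5 at P10 against E15.5 reversed to 0.33 with the mean of its probe sets, which were called both ways. Lists were run with the percentile 30 filter, quantile normalisation, ribosomal centring, the replicate block, fits without 1 array, fry, an estimated correlation and the later choices. Of 67 called lists, 18 kept their call under these, and 49 lost it with an estimated correlation between genes, which left 4, 6 and 8 lists in the 3 contrasts. The mixed form of fry called 34 at P10 against E15.5. The endothelial median reversed without P5 arrays 2 and 3, to -0.053 at P5 against E15.5 and 0.22 at P10 against P5. Quantile normalisation gave 6132 higher at P5 and 7858 higher at P10 than at E15.5, and centring on all genes 6085 higher at P10 than at E15.5 and 854 higher at P10 than at P5. The cause was not tested. A floor at percentile 30, which differs between arrays by construction, gave 7360 lower at P5 and 7616 lower at P10 than at E15.5 and 11684 for the F test. Stricter thresholds call fewer by construction: at 2-fold 1435 higher and 1356 lower at P5, 1807 and 1636 at P10 against E15.5, 79 and 162 at P10 against P5 and 3719 by F, and at adjusted p under 0.01 165 and 216 at P10 against P5. At P10 against P5, 210 and 231 were called without moderation and 337 and 372 with only those stages, where fewer arrays estimate the spread. Without P5 arrays 2 and 3, 336 were lower at P10 than at P5 and 2056 differed between intervals, with no replicate at P5. Leaving out 1 array gave 3007 to 3689 higher and 2968 to 3485 lower at P5 against E15.5, 3448 to 4101 and 3220 to 3794 at P10 against E15.5, and 250 (without P10 array 2) to 802 (without P5 array 3) and 336 to 583 at P10 against P5. The F count ran from 6633 to 8191. With the replicate block the counts were 3452 and 3434, 3852 and 3588, and 409 and 484, with 7406 by F. Filters, stricter thresholds and separate probe sets gave no value for single named genes, except as probe sets compared for the 14 genes with several. Signal over background limits genes near the floor, such as Ptprc.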

Other observations

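Several genes of antigen presentation and the interferon response were higher at P5 than at E15.5. The proteasome subunit genes Psmb8 (4.43 ± 0.33) and Psmb9 (4.09 ± 0.37), which shape peptides for MHC class I, rose, as did the interferon-induced GTPase genes Iigp1 (4.22 ± 0.23) and Irgm1 (3.32 ± 0.38). In the antigen presentation list, 5 rose and 0 fell of 15 (5 and 0 adjusted over the list alone). The list had camera adjusted p = 0.00723 and adjusted p = 0.594 with an estimated correlation. At P10 against E15.5 it did not pass (camera adjusted p = 0.374 and adjusted p = 0.852 with an estimated correlation). From P5 to P10 camera called the list lower (adjusted p = 0.000298 and adjusted p = 0.427 with an estimated correlation). In that contrast 0 rose and 0 fell of 15 (0 and 2 adjusted over the list alone). On P5 arrays 1, 2 and 3 the list had a median log2 signal of 7.24, 9.66 and 6.67. On the P10 arrays this median lay between 6.79 and 7.02, so the stages overlapped. In the interferon list, 7 rose and 0 fell of 23 (6 and 0 adjusted over the list alone). It had camera adjusted p = 0.0106 and adjusted p = 0.666 with an estimated correlation, a call that ended without P5 array 2 (adjusted p = 0.0889), and at P10 against E15.5 it did not pass (camera adjusted p = 0.0964 and adjusted p = 0.825 with an estimated correlation). P5 array 2 stood apart here: the members' median difference from P5 array 1 was 1.23 for the interferon list and 1.06 for the antigen presentation list. In the complement and acute phase list, 8 rose and 3 fell of 18 (8 and 3 adjusted over the list alone), with the haptoglobin gene Hp higher (5.03 ± 0.25) and the collectin gene Colec11 lower (-2.28 ± 0.18). It had camera adjusted p = 0.0407 and adjusted p = 0.332 with an estimated correlation, and the call ended without E15.5 array 2, P5 array 2 or P5 array 3 (adjusted p from 0.0567 to 0.0716). From P5 to P10, 0 rose and 7 fell of 18 (0 and 10 adjusted over the list alone), with camera adjusted p = 6.07e-07 and adjusted p = 0.0510 with an estimated correlation. Among chemokines and cytokines, 7 rose and 3 fell of 25 (7 and 3 adjusted over the list alone), including Il18 (3.20 ± 0.36) and Il33 (-1.16 ± 0.23), and the list did not pass (camera adjusted p = 0.184 and adjusted p = 0.594 with an estimated correlation).

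Several cholesterol biosynthesis genes fell between P5 and P10. Sqle, the squalene epoxidase gene, differed by -2.06 ± 0.22 and Cyp51, the lanosterol demethylase gene, by -1.77 ± 0.14. In that list, 0 rose and 9 fell of 19 (0 and 16 adjusted over the list alone), with a median of -1.04 (camera adjusted p = 4.84e-13 and adjusted p = 0.114 with an estimated correlation). Against E15.5 at P5 the list did not pass (camera adjusted p = 0.0897 and adjusted p = 0.735 with an estimated correlation). In the glycolysis and hypoxia list at P10 against E15.5, 9 rose and 9 fell of 24 (10 and 9 adjusted over the list alone), with the hypoxia-responsive gene Egln3 higher (3.22 ± 0.22) and the pyruvate kinase gene Pkm lower (-1.35 ± 0.079). Its median was -0.11 and its mean 0.11, opposite in sign, and it did not pass (camera adjusted p = 0.940 and adjusted p = 0.971 with an estimated correlation). In the portal fibroblast list at P5 against E15.5 genes went both ways: 5 rose and 6 fell of 17 (6 and 6 adjusted over the list alone), with Fbln1 lower (-1.20 ± 0.081) and Msln, which mesothelial cells also express, higher (2.52 ± 0.26).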
